A study of Homo sapiens with 10 samples.

How the data were processed

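RNA of THP1 cells carrying the inducible RUVBL2 hairpin was analysed, with 5 libraries from cells in medium and 5 from cells exposed to doxycycline at 1 µg/ml for 4 days. Total RNA was made into indexed libraries with the Illumina TruSeq RNA v2 chemistry, per the labels' protocols. STAR, bedtools, HTSeq and DESeq2 and the genome build hg19 are named in the submitters' processing notes, without versions, roles or order. Which program aligned the reads and which counted them, the annotation, and whether strand was used are not given in the sources used here.

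A single comparison table was analysed, with 1 line for each of 23710 genes and no values per library. The log2 fold change and its standard error, on the log2 scale, are the authors' values, per the file headers. The q value is an adjusted p-value as deposited by the authors. The mean count is the authors' average over libraries, per the file headers, and its scaling is not stated there. Each gene also carries a mark: 12149 were marked OK, 11129 Low and 432 Outlier, and 5660 genes had a mean count of 0. All genes marked Low had a mean count of 9.99 or less, and genes marked Low or Outlier carry a q value of 1. Adjusted p-values recomputed from the fold change and its standard error by a normal two-sided test with Benjamini-Hochberg adjustment over genes marked OK differed from the listed q values by at most 0.00442, so the marks Low and Outlier were left out of that adjustment. The standard error did not exceed 0.298 in any group of marks, and fold changes at very low mean counts lay near 0 (median absolute log2 fold change 0.0593 at means above 0 and under 1). Fold changes shrunken toward 0 would look the same, so the folds of low genes may be understated.

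The sum of mean counts was 7545651 over all genes. Total counts per library were not analysed here, so no interval that needs them is given, and the precision of each value is the authors' standard error. Outlier libraries, duplicate libraries and batches could not be looked for without values per library.

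Genes with a listed q value under 0.05 were counted as changed. No test of single genes was made here in place of the authors' test, because the design fixed before the data were examined foresaw this for a comparison table. The tests it foresaw for values per library did not apply. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the ratio of fold change to standard error, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 30 lists. A correlation could not be estimated without values per library, and a preset of 0.05 was used as the alternative. With it 9 of the 12 lists called kept an adjusted p under 0.05. The share of each list that rose or fell was compared with that of the other tested genes by Fisher's exact test, two-sided, adjusted over lists and directions. Median fold changes of lists were set against 10000 random lists of the same size matched on mean count in 20 bins. Counting and plotting used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

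The 31 lists were fixed before the data were examined. They cover RUVBL partners and R2TP, INO80, SRCAP and TIP60 subunits, PIKK kinases, small nucleolar RNPs, the MLL-AF9 and HOXA programme, MYB targets, MYC targets, G1/S and DNA replication, G2/M and mitosis, cell-cycle inhibitors and p53 targets, the BCL2 family, monocyte and macrophage maturation, myeloid progenitor and granule genes, NF-kB and inflammatory cytokines, interferon-stimulated genes, MHC class II, immediate-early genes, ATF4 and the unfolded protein response, heat shock, cholesterol synthesis, glycolysis and hypoxia, the respiratory chain, the mitochondrial ribosome, cytosolic ribosomal proteins, histones, DNA repair, telomerase and shelterin, and markers of erythroid, lymphoid, and fibroblast or epithelial cells. A list of mitochondrially encoded transcripts had 0 members in the table and was left out. Of 869 list entries, 854 were found in the table, 4 of them through an older symbol in the RefSeq gene table of GRCh38.p14. The NF-kB list held IL8 under its older and its newer symbol, and it was counted once, which left 853 members. Because that assembly is not the one in the submitters' notes, it was used for names and gene order only and no coordinates are printed. Length and GC content were those of the longest GENCODE transcript of each gene, matched by symbol.

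The genes named were RUVBL2, RUVBL1, MYB, MYC, BCL2, CDK6, MEIS1, HOXA9, TERT, CDKN1A, CD14, ITGAM and MPO, then the 10 that rose most and the 10 that fell most by log2 fold change among genes with an adjusted p under 0.05 and a mean count of at least 100, then up to 4 members of each list with the smallest adjusted p. Other genes were named after their values were seen.

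The scripts were tested on simulated data for the comparison of doxycycline with medium. Single genes were drawn with the standard errors of the 12149 tested genes, and lists from statistics with the spread observed over genes. With 50 genes changed at each size, 18% were recovered at a log2 fold change of 0.25, 66% at 0.5, 96% at 1 and 100% at 2, with 4 false calls among 144. Far fewer genes were changed there than the 3829 called in the data, which made the adjusted threshold stricter. Recovery of small changes in the data may therefore be understated. In 100 draws with 3 shifted lists, 97% of the shifted lists were recovered and 0.333% of the others were called. Genes were drawn independently of each other there. The rate of false calls therefore does not cover lists whose genes vary together, as they may in the data.

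Alternatives covered the filter on mean count, the adjustment of p, the thresholds, the list statistic, the preset correlation and the background. After the data were seen, alternatives with outlier-marked genes included, with fold changes centred to equal summed counts, and with the trend on mean count, length and GC content removed were added. Length and GC content were found for 11835 of the 12149 tested genes (97.4%).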

Results

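THP1 is an established human monocytic leukaemia cell line. The cells carried TRIPZ, a lentiviral vector that expresses a short hairpin RNA from a doxycycline-inducible promoter, with a hairpin directed against RUVBL2. RUVBL2 is an AAA+ ATPase that works with RUVBL1 in the R2TP co-chaperone and in the INO80, SRCAP and TIP60 chromatin complexes. Messenger RNA was sequenced from 5 libraries of cells kept in medium and 5 libraries of cells given doxycycline at 1 µg/ml for 4 days, described as 5 pairs. The labels do not say whether the libraries of a group came from separate cultures. The authors' adjusted p-values of single genes therefore measure the spread between these libraries, which may be technical. Whether their test used the pairs is not known. Adjusted p-values of gene lists and families compare genes with other genes, from a single statistic per gene, and do not measure replication over libraries. The values analysed here are the authors' comparison of both groups and not values per library. The authors' deposited table gives, for 23710 genes, the mean count over libraries, the log2 fold change, its standard error (SE) and an adjusted p. The mean counts sum to 7545651 over all genes, and the depth of each library is not known from them. Of the 23710 genes, 12149 were tested, 11129 were marked as low (mean count under 10) and 432 were marked as outliers and left untested.

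The comparison asks how the transcriptome of THP1 cells changed when the RUVBL2 hairpin was induced. RUVBL2, the targeted gene, had the lowest log2 fold change of all 12149 tested genes in the authors' deposited table, -1.75 (SE 0.11), with the adjusted p listed at 0. On a linear scale this was 0.297 times the level in medium, a change of -70.3%, at a mean count of 551. The header of the table does not state the direction of the fold change, and the name under which the table was deposited puts the medium group first, which could be read as the opposite ratio. It was read here as doxycycline over medium because the gene targeted by the hairpin would otherwise have risen, and every direction below rests on that reading. The target therefore does not check the group labels independently, and its value per library was not analysed here. RUVBL1, the partner ATPase, fell as well, with a log2 fold change of -0.47 (SE 0.07, adjusted p = 1.4e-09) in the authors' deposited table.

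With the hairpin induced, interferon-stimulated genes rose and genes of DNA replication, mitosis, cytosolic ribosomes and cholesterol synthesis fell. Of the 12149 tested genes in the authors' deposited table, 3829 (31.52%) had an adjusted p under 0.05, of which 1893 rose and 1936 fell. Most of these changes were small, with a median absolute log2 fold change of 0.37. Among the 127 genes that also changed by a log2 fold of at least 1, 100 rose and 27 fell. Precision followed the mean count: the median SE in the authors' deposited table was 0.20 for tested genes with a mean count from 10 to 100, where 19.8% passed, 0.10 from 100 to 1000, where 33.5% passed, and 0.07 above that, where 48.5% passed. A gene that did not pass at a low mean count was therefore not detectably changed at this depth. No group with doxycycline and another hairpin was analysed here, so the effect of doxycycline itself is contained in each value.

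Among genes with a mean count of at least 100, the largest rise was that of LOX, a lysyl oxidase that cross-links collagen and elastin, with a log2 fold change of 3.25 (SE 0.23, adjusted p = 1.46e-42) in the authors' deposited table. SIGLEC1, a sialic acid-binding receptor of macrophages that responds to interferon, followed at 2.76 (SE 0.16) in the authors' deposited table. At such mean counts, the other genes in the top 10 by log2 fold change in the authors' deposited table were ANTXR1 (2.12), MX1 (2.12), DUSP4 (2.02), IFI6 (2.01), OAS3 (1.86), CLCN5 (1.69), DUSP27 (1.61) and FUCA1 (1.61). After RUVBL2, the largest falls at a mean count of at least 100 in the authors' deposited table were those of VIT (log2 fold change -1.46, SE 0.21), the WNT ligand gene WNT7B (-1.18, SE 0.20) and MARC1 (-1.12, SE 0.12). They were followed in the authors' deposited table by BMP8B (log2 fold change -1.05), B4GALT2 (-1.02), the ribonucleotide reductase subunit RRM2 (-0.99), CPNE7 (-0.98), PLAC8 (-0.97) and the receptor tyrosine kinase FLT3 (-0.96). All 20 genes had an adjusted p of 4.83e-08 or lower.

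**Figure D1:**
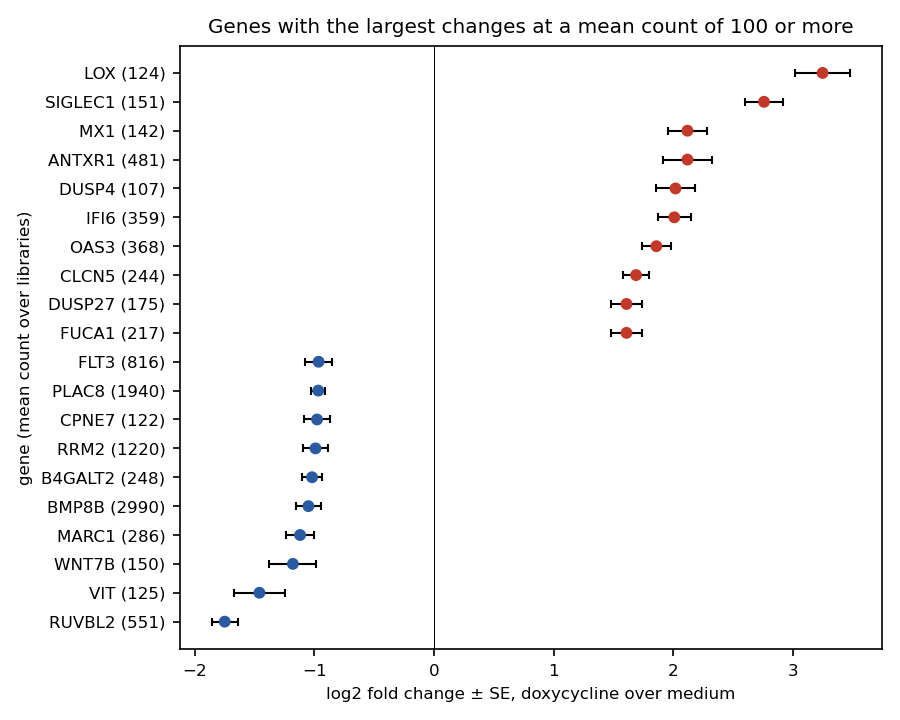
Log2 fold change (horizontal axis, doxycycline over medium) of the 10 genes that rose most and the 10 that fell most at a mean count of at least 100, from the authors' deposited table. Points are the fold changes, bars the authors' SE, and the mean count over libraries stands in brackets after each gene. LOX lies highest at 3.25 and RUVBL2 lowest at -1.75.

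Interferon-stimulated genes formed the list with the highest median change. Of the 36 tested members, 26 rose, 1 fell and 9 did not pass, and 30 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.76 (limma cameraPR, adjusted p = 9.914e-23 over 30 lists). In the authors' deposited table the antiviral genes OAS3, MX1 and IFI6 had log2 fold changes of 1.86 (SE 0.12), 2.12 (SE 0.17) and 2.01 (SE 0.14), and IRF9, the DNA-binding subunit of the interferon-activated ISGF3 complex, 1.24 (SE 0.10). The member that fell was the immunoproteasome subunit gene PSMB8, chosen after its value was seen, at a log2 fold change of -0.22 in the authors' deposited table. MHC class II genes, which interferon gamma induces, moved both ways: of 8 tested, 2 rose (HLA-DRB1 and HLA-DQB1) and 1 fell (HLA-DRA), with the same counts when adjusted over the list alone (list adjusted p = 0.9438).

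Genes of monocyte and macrophage maturation also rose as a list. Of 22 tested members 9 rose, 1 fell and 12 did not pass (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.23 (limma cameraPR, adjusted p = 3.675e-04). The authors' deposited table lists log2 fold changes of 1.40 (SE 0.17) for ITGAM (CD11b), 0.96 (SE 0.10) for ITGAX (CD11c), 0.90 (SE 0.09) for the lysosomal protease gene CTSD and 0.83 (SE 0.13) for CTSB. CD14, the monocyte co-receptor for lipopolysaccharide, did not pass, at 0.14 (SE 0.28, adjusted p = 0.751) in the authors' deposited table. The member that fell was IRF8, chosen after its value was seen, at -0.39 (SE 0.11) in the authors' deposited table. Of the 35 members with a mean count of at least 10, 13 (37.1%) were marked as outliers and left untested, against 3.34% of other genes. The median log2 fold change of these 13 was -0.105, against 0.23 for the tested members. The share of members that rose exceeded that of other tested genes (Fisher's exact test, two-sided, adjusted p = 0.0192), but not once outlier-marked genes were included (adjusted p = 0.155) or only genes with a mean count of at least 100 were taken (adjusted p = 0.056). Myeloid progenitor and granule genes did not move as a list (15 tested, 2 rose and 3 fell, 2 and 4 adjusted over the list alone, list adjusted p = 0.4017). Among them the authors' deposited table gives log2 fold changes of -0.78 (SE 0.17, adjusted p = 4.79e-05) for the granule enzyme gene MPO and -0.75 (SE 0.15) for the stem cell factor receptor gene KIT.

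Cell-cycle genes fell. Of 40 tested genes of the G1/S transition and DNA replication, 37 fell, none rose and 3 did not pass (39 fell adjusted over the list alone), with a median log2 fold change of -0.37 (limma cameraPR, adjusted p = 5.787e-28). Of 39 tested genes of G2/M and mitosis, 30 fell and 9 did not pass (33 fell adjusted over the list alone), with a median of -0.34 (adjusted p = 6.304e-13). In the authors' deposited table the replicative helicase genes MCM7, MCM4 and MCM3 had log2 fold changes of -0.77 (SE 0.05), -0.43 (SE 0.04) and -0.52 (SE 0.05). The mitotic regulators CCNA2, UBE2C, CDK1 and PLK1 lay at -0.53, -0.51, -0.48 and -0.49 in the authors' deposited table. DNA repair genes also fell, with 14 of 32 lower, none higher and 18 not passing (18 fell adjusted over the list alone), at a median of -0.20 (adjusted p = 1.486e-04), among them MSH6, XRCC3, CHEK2 and FANCD2.

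Genes of protein synthesis fell by small amounts. Of 73 tested cytosolic ribosomal protein genes 67 fell, none rose and 6 did not pass (69 fell adjusted over the list alone), with a median log2 fold change of -0.30 (limma cameraPR, adjusted p = 4.239e-51). RPS12 and RPS6, for example, had log2 fold changes of -0.54 (SE 0.04) and -0.46 (SE 0.04) in the authors' deposited table. Ribosomal proteins have many processed pseudogenes, so their values depend on how the authors' counting treated shared reads. Mitochondrial ribosome genes fell too (18 of 49, with 2 higher and 29 not passing, 20 and 2 adjusted over the list alone, median -0.17, list adjusted p = 0.004154), but the list's adjusted p was 0.09963 with a preset correlation of 0.05 in place of 0.01. Of 15 genes of box C/D and H/ACA small nucleolar RNPs, whose assembly uses RUVBL1 and RUVBL2, 7 fell and 2 rose (the same adjusted over the list alone), with a median of -0.16 (list adjusted p = 0.03521, but 0.1138 with a preset correlation of 0.05). FBL, the methyltransferase of box C/D particles, lay at -0.52 (SE 0.06) in the authors' deposited table. TCOF1, which is on the list but is not a core protein of the particles, lay at -0.46 (SE 0.05). Among core protein genes, NOP58 did not pass, at 0.07 (SE 0.07), and NOP10 rose, at 0.16 (SE 0.06), in the authors' deposited table.

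MYC targets fell, with 18 of 28 tested lower, none higher and 10 not passing (19 fell adjusted over the list alone), at a median log2 fold change of -0.27 (limma cameraPR, adjusted p = 7.317e-10). Examples in the authors' deposited table were FASN at -0.78 (SE 0.07), the nucleolar protein gene NCL at -0.37 (SE 0.04) and NPM1 at -0.36 (SE 0.05). MYB and its activated targets fell as well: 6 of 13 tested members fell, none rose and 7 did not pass (6 fell adjusted over the list alone), at a median of -0.29 (adjusted p = 0.004154), while 7 of the 20 members with a mean count of at least 10 were marked as outliers. The MYB list shares cell-cycle genes such as CCNB1 and TOP2A with the wider cell-cycle programme. The other members that fell are on further lists too: BCL2 on that of the BCL2 family, and KIT, MPO and AZU1 on that of myeloid progenitor and granule genes. The fall of the MYB list is therefore not separate from the changes of those lists. MYC and MYB themselves were marked as outliers in the authors' deposited table and carry no test, with log2 fold changes of -0.80 (SE 0.18) and -0.15 (SE 0.29). CDK6 was likewise marked, at 0.00 (SE 0.23) in the authors' deposited table.

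Cholesterol synthesis genes had the lowest median of all lists, -0.47, with 13 of 18 tested members lower, none higher and 5 not passing (15 fell adjusted over the list alone, limma cameraPR adjusted p = 2.035e-04). Of the 24 members with a mean count of at least 10, 6 (25%) were marked as outliers. The authors' deposited table gives log2 fold changes of -0.95 (SE 0.22) for DHCR7, -0.80 (SE 0.16) for ACAT2, -0.68 (SE 0.17) for HMGCS1 and -0.47 (SE 0.10) for FDPS. Glycolysis and hypoxia genes had 7 of 24 lower, 1 higher and 16 not passing (the same adjusted over the list alone, median -0.17, list adjusted p = 0.03755, but 0.1517 with a preset correlation of 0.05). LDHA fell and PKM rose among them, at -0.45 (SE 0.10) and 0.36 (SE 0.08) in the authors' deposited table.

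Transcripts of the complexes that contain RUVBL2 did not move as lists. Only RNA was measured, so the proteins and the assembly of these complexes were not examined. Of 16 RUVBL partners and R2TP genes, 4 fell, 2 rose and 10 did not pass (the same adjusted over the list alone, list adjusted p = 0.2999). RUVBL1, PIH1D1 and URI1 fell and ECD rose, the last at a log2 fold change of 0.52 (SE 0.11) in the authors' deposited table. Of 29 INO80, SRCAP and TIP60 subunits 6 fell and 1 rose (the same adjusted over the list alone, list adjusted p = 0.6413). None of 5 tested PIKK kinase genes, whose proteins are R2TP clients, passed over all genes or adjusted over the list alone (list adjusted p = 0.9438). TERT, the telomerase catalytic subunit, fell by 1.41 on the log2 scale (SE 0.22, adjusted p = 4.72e-09) at a mean count of 27.4 in the authors' deposited table, while the telomerase and shelterin list did not move (15 tested, 4 fell and 2 rose, the same adjusted over the list alone, list adjusted p = 0.7365).

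Lists of leukaemia and survival genes held single changes without a shift of the whole list. Of 21 tested genes of the MLL-AF9 and HOXA programme, which THP1 cells carry through their KMT2A fusion, 7 fell and 3 rose (the same adjusted over the list alone, list adjusted p = 0.2753). HOXA9 lay at 0.05 (SE 0.11, adjusted p = 0.798) in the authors' deposited table, and MEIS1 was marked as low with a mean count of 0.414. In the BCL2 family 2 of 11 fell and none rose (1 fell adjusted over the list alone, list adjusted p = 0.646), with the anti-apoptotic gene BCL2 at -0.31 (SE 0.05, adjusted p = 1.47e-10) in the authors' deposited table. Among cell-cycle inhibitors and p53 targets 5 rose, 2 fell and 15 did not pass (5 and 2 adjusted over the list alone, list adjusted p = 0.2999), and the list's median of -0.04 and its mean of 0.13 differed in sign. SESN1 and ZMAT3 rose within it, at 1.18 (SE 0.11) and 1.21 (SE 0.15) in the authors' deposited table. CDKN1A, the p21 gene, was marked as an outlier and carries no test, at 0.85 (SE 0.19) in the authors' deposited table.

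The remaining lists did not pass. In NF-kB and inflammatory cytokine genes 3 of 10 tested members rose and none fell (the same adjusted over the list alone, median 0.24, list adjusted p = 0.05922), and 11 of the 21 members with a mean count of at least 10 were marked as outliers. Immediate-early and AP-1 genes had 5 tested members, of which 1 fell (1 adjusted over the list alone, list adjusted p = 0.6792), because 14 of 19 were marked as outliers. ATF4 and unfolded protein response genes split into 3 higher and 5 lower of 26 (list adjusted p = 0.252), and heat shock genes had 4 lower of 17 (list adjusted p = 0.2103), with the same counts adjusted over each list alone. Nuclear-encoded respiratory chain genes, examined because doxycycline inhibits mitochondrial translation, had 3 higher and 10 lower of 50 (3 and 9 adjusted over the list alone, list adjusted p = 0.6865). Replication-dependent histones had 2 higher and 2 lower of 6 (the same adjusted over the list alone, list adjusted p = 0.9438), with a negative median and a positive mean statistic. Of the 35 histone genes on the list, 29 were marked as low, so whether histone genes changed as a group could not be told. Markers of other cell types were mostly low: 4 erythroid and megakaryocyte markers were tested and none passed (list adjusted p = 0.8958). Of 6 tested genes on the lymphoid list 2 rose, CD4 at a mean count of 1750 and EBF1 at 15.9 in the authors' deposited table (list adjusted p = 0.2353). Among 3 fibroblast and epithelial markers 1 rose (2 adjusted over the list alone, list adjusted p = 0.646).

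**Figure D2:**
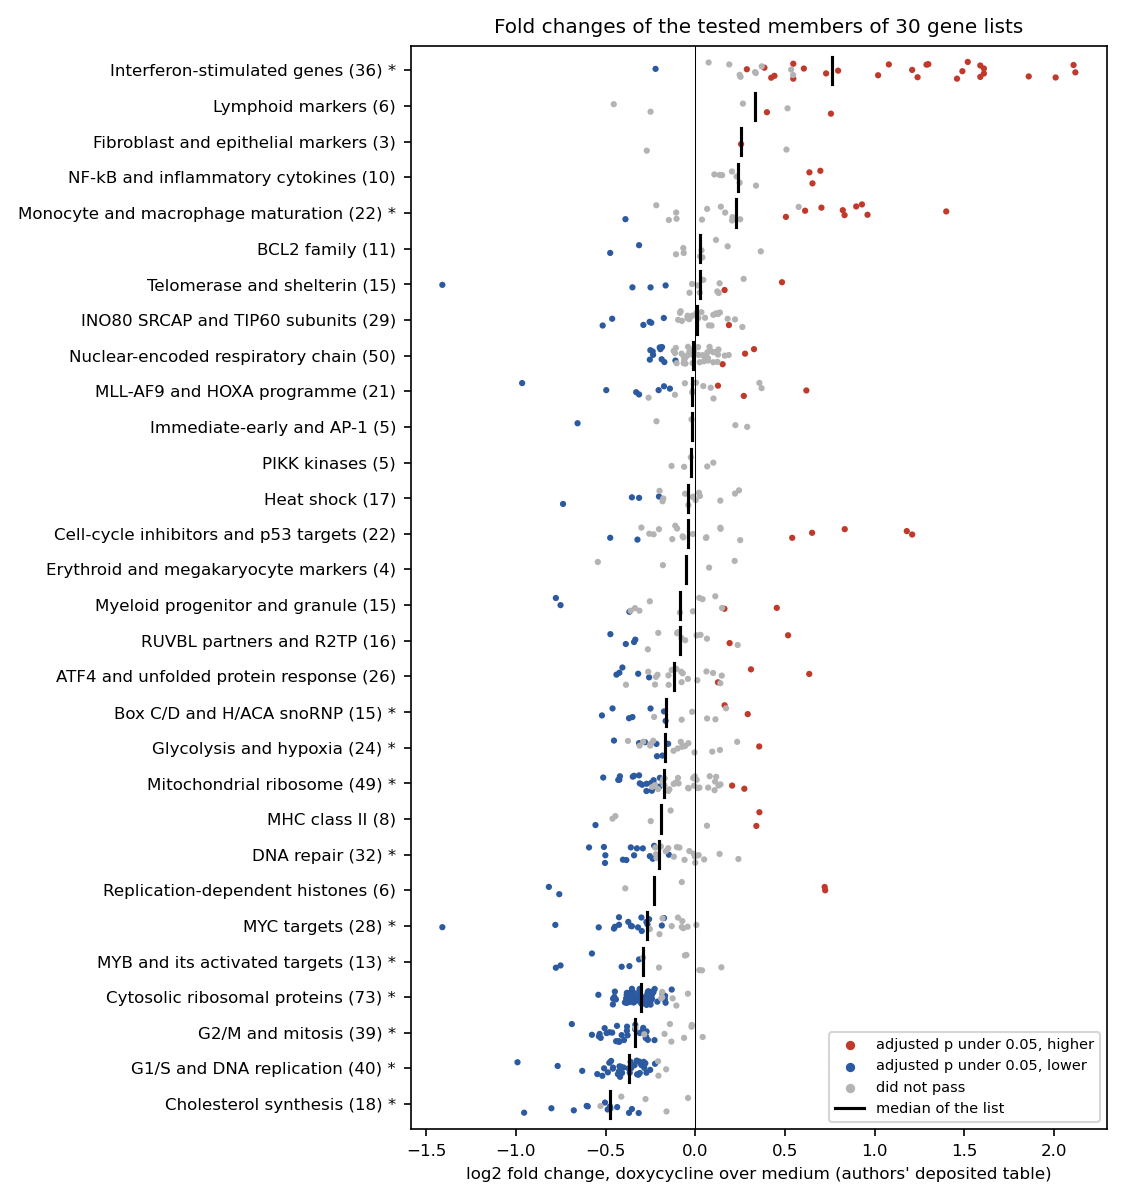
Log2 fold change (horizontal axis, doxycycline over medium, from the authors' deposited table) of each tested member of the 30 gene lists, with the number tested in brackets. Each point is a gene, red or blue where its adjusted p was under 0.05 and it was higher or lower, grey where it did not pass, and the vertical scatter within a list has no meaning. Black bars are list medians, from 0.76 for interferon-stimulated genes to -0.47 for cholesterol synthesis, and an asterisk marks the 12 lists with an adjusted p under 0.05.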

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

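All tests in this part were chosen after the results were seen. Genes marked Outlier carry no test in the authors' deposited table and were left out of the comparisons above, apart from an alternative for the monocyte and macrophage list. With the mark ignored, 57 of the 432 had an adjusted p under 0.05 recomputed from the fold change and its standard error, 28 of them higher and 29 lower with doxycycline. The fold change of a marked gene may rest on a single library, which cannot be checked without values per library. None of the 57 is therefore counted as changed. The 57 include MYC (log2 fold change -0.80, recomputed adjusted p = 7e-05) and CDKN1A (0.85, recomputed adjusted p = 6.09e-05), from the authors' deposited table. Chosen after their values were seen, LGALS3BP (1.68, SE 0.26), CD82 (1.30, SE 0.19) and GPNMB (1.14, SE 0.18) lay highest among the 57 by log2 fold change in the authors' deposited table, and the granule protease gene PRTN3 (-1.18, SE 0.22) lay near the lowest.

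The outlier marks gathered in particular gene groups, with more marks than among other genes in 9 of 30 lists (Fisher's exact test, two-sided, adjusted over lists). Of all genes with a mean count of at least 10, 3.43% were marked, against 14 of 19 immediate-early and AP-1 genes (73.7%, exact 95% interval 48.8 to 90.9%), among them FOS, JUN, EGR1 and NR4A1. A tendency of marks to fall on genes with higher counts is argued against, since the highest of 10000 random lists matched on mean count held 6 marked genes against 14. A response shared by all libraries of a group was not settled. The median absolute ratio of fold change to standard error of the marked immediate-early genes was 0.834. Their median standard error was 0.26, against 0.11 for tested genes and 0.245 for all genes marked Outlier. A wide spread thus came with the mark, and it could hide a change. A library or pair of libraries in another state stays open because 0 columns of values per library were analysed, and no biological explanation was tested.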

How the results depend on the processing

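The alternatives with outlier-marked genes included, equal summed counts and the trend removed were chosen after the data were seen. RUVBL2 stayed lower and past its threshold in every setting run. The count of changed genes, 3829, lay between 2642 and 4589 under other filters, other adjusted p thresholds and the added settings, except for 1094 with Bonferroni adjustment and 127 with a log2 fold of at least 1, both stricter by construction. Equal summed counts raised every log2 fold change by 0.02 and gave 2111 higher and 1709 lower. Of the 12 lists called, 9 were called in every setting. Small nucleolar RNPs had adjusted p = 0.1138 with a preset correlation of 0.05, 0.2586 on log2 fold changes, 0.1475 on ranks, 0.06792 at a mean count of at least 100, 0.06553 with the trend removed and 0.08399 against random lists. Glycolysis and hypoxia had 0.1517, 0.1213, 0.06815, 0.1877 and 0.05399 in the same settings, ranks excepted. The mitochondrial ribosome had 0.09963 with a preset correlation of 0.05. NF-kB genes passed on log2 fold changes (0.00717) and on ranks (0.02276), and the cause of these differences was not tested. Fisher's exact test found 11 lists and directions enriched, and 1 at a log2 fold of at least 1 (interferon-stimulated genes, higher). It found 9 at a mean count of at least 100, where the fall of the MYB list had adjusted p = 0.1198, and 10 with outlier-marked genes included. No paired analysis was possible because the table holds one comparison and no values per library. Leaving out replicates, other tools, normalizations and pseudocounts, and other splits of the samples could not be run for the same reason. Depth limits genes with low mean counts most.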

Other observations

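All tests in this part were chosen after the results were seen. Grouping tested genes by the stem of their symbol gave 210 families with at least 8 members, of which 10 had an adjusted p under 0.05 (limma cameraPR), 5 higher and 5 lower. Families were tested with the preset correlation of 0.01 only. Among families with no member on a fixed list, sialic acid-binding SIGLEC receptor genes rose (7 of 11 rose, 1 fell, median log2 fold change 0.67, adjusted p = 1.04e-04), and next to SIGLEC1 the authors' deposited table gives SIGLEC11 at 1.07 (SE 0.26) and SIGLEC7 at 0.93 (SE 0.15). ADAM metalloprotease genes were higher (4 of 10 rose, none fell, adjusted p = 0.00267), with ADAM9 at 1.45 (SE 0.07) in the authors' deposited table. Neighbouring SIGLEC genes are similar in sequence, so shared reads make their single values uncertain.

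Genes with the symbol stem EEF, shared by translation elongation factors and genes named after them, fell together (7 of 8 fell, none rose, median log2 fold change -0.32, adjusted p = 1.5e-06). So did small nucleolar RNA host genes (8 of 13 fell, none rose, median -0.42, adjusted p = 0.00139). In the authors' deposited table EEF1B2 lay at -0.54 (SE 0.04), EEF2 at -0.42 (SE 0.06), SNHG8 at -0.59 (SE 0.10) and SNHG5 at -0.46 (SE 0.06). LOX, PRR16 and ZNF608 ranked 2, 4 and 5 among all tested genes by log2 fold change and lie near each other on chromosome 5, at 3.25 (SE 0.23), 2.75 (SE 0.25) and 2.35 (SE 0.24) in the authors' deposited table. Of the 6 other tested genes between PRR16 and ZNF608, 1 passed, PPIC at 0.61 (SE 0.15) in the authors' deposited table. Across genes, which are not independent replicates, the statistics of 11913 neighbouring pairs had a Spearman rho of 0.0777, against a highest value of 0.0362 in 1000 shuffles of gene order.

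MIR30A, a microRNA gene, had the highest log2 fold change of all tested genes in the authors' deposited table, 3.91 (SE 0.25) at a mean count of 42.8. The hairpin of the TRIPZ vector is embedded in a miR-30 scaffold, and a candidate explanation is that reads of the induced vector transcript were counted at MIR30A. The neighbouring genes do not decide it: of the 6 nearest tested genes, 3 on each side, 0 rose by a log2 fold of 1 or more, but 0.823% of all tested genes did, so that none of 6 would do so by chance in 95.2% of cases. Higher transcription across the locus was not settled either, because LINC00472, the nearest annotated gene other than a microRNA, had a mean count of 0.829. Reads were not analysed here, and the vector remains an untested hypothesis.

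The rise of interferon-stimulated genes was weighed against 3 explanations. A trend on mean count, length or GC content as the whole cause is argued against, since the list had an adjusted p of 9.928e-24 with the trend removed. Doxycycline or an induced hairpin in itself cannot be told apart from loss of RUVBL2, because 0 groups with doxycycline and another hairpin were analysed. More interferon transcripts could not be examined, because 0 of the 22 interferon genes in the table had a mean count of at least 10, and the highest mean among them was 0.307. An effect of RUVBL2 loss therefore stays open as a hypothesis beside the untested effect of doxycycline and of the hairpin.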
